A study of Mus musculus with 36 samples.

How the data were processed

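RNA of whole lung from 36 male BALB/c mice of 8 weeks, WT or SCID, uninfected or 2, 3, 4, 8 or 12 days after 500 Nippostrongylus brasiliensis larvae, was hybridised to Affymetrix Mouse430_2 arrays. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns and read into probe-set signals with GCOS 1.2, with MAS5 among the processing tools. The deposited values are in the unit intensity, on a linear scale, for 45101 probe sets. The mean signal of each array without its lowest and highest 2% was 500, so the authors had scaled the arrays to a common level. The files used here hold no detection calls, scan dates or batch labels. Signals ran from 0 to 70215.1, array medians from 155.6 to 200.7, and no 2 arrays were copies of each other (highest r 0.9679). The number of arrays limits the precision.

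The choices that follow, with the comparisons, gene lists, alternatives and the rule for naming genes, were made before the data were examined, apart from the alternatives named as later ones. Signals were used as scaled by the authors and transformed as log2(signal + 16), where 16 is the power of 2 nearest to the 10th percentile of all signals (13.6). A probe set was kept if it reached 109.1, the 40th percentile, in at least 3 arrays, which left 32872. The platform table gives 1 symbol for 34958 probe sets, several for 932 and none for 9211. The gene IDs of 34754 probe sets matched the mouse gene table, which was used for older symbols. Probe sets with no or several symbols were left out, leaving 27046, and each gene was represented by the probe set with the highest mean log2 value, sets ending in _x_at only where there was no other, which gave 14970 genes.

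The 12 groups of 3 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, 24 residual and 6.65 prior degrees of freedom). There were 16 contrasts: SCID against WT uninfected, each of the 5 days against the uninfected mice of the same strain, and, for each day, the SCID change minus the WT change, called the response difference. P-values were adjusted by Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. All p are two-sided. Genes called in both strains in one direction were counted at each day, beside n1 times n2 over the number of genes tested in each direction. The tests were tried on simulated arrays, drawn as independent normal noise around the mean of each gene with its residual spread. Changes of known size were added to the simulated SCID day 4 arrays. Such arrays hold no structure shared between genes or arrays, so real data may give other shares. Of genes changed by 0.5, 1 and 2 on the log2 scale, 31.8%, 65.7% and 95.5% were recovered in the comparison with uninfected mice and 7.6%, 47.8% and 88.1% in the response difference. In them 5.1% and 4% of the calls were of unchanged genes.

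A total of 32 gene lists (immune cells, lung cells, response pathways and other tissues, 494 distinct genes) were fixed from textbook knowledge. Of their genes 417 were tested, 33 lay below the filter and 44 were not in the probe table. Lists with fewer than 3 genes tested were left out. The remaining 31 were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 496 list and contrast pairs; members called are counted over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

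Genes are named by a rule. Its first part takes, in each family of comparisons and at each day, the 5 largest rises and 3 largest falls (12 and 12 for the uninfected mice) among called genes whose 3 arrays of one group all lie beyond the 3 of the other, a condition not asked of the response difference, and whose brighter group reaches the filter signal. Its second part takes up to 4 called members of each list per family. Its last part always takes 19 genes (among them Retnla, Chil3, Arg1, Il4, Il5, Il13, Il33, Clca1 and Prkdc). Any list member may be named to show that it did not pass. Where space was short the largest changes were to come first, but this was not always kept. For example, the falls of Nsun5 (-1.83) and Sec1 (-1.68) in WT mice at day 12 are left out below, while smaller ones are given.

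Every count was refitted with a pseudocount of 4 or 64, with no filter, with a filter at 269.9 (the 60th percentile), with quantile normalization or median centring, without a trend and with array weights. It was refitted also with the replicate number as a block, with only the groups compared in the fit, with the probe sets of a gene averaged, and without each array in turn. The spread is pooled over all groups, so a group left with 2 arrays adds little to it and a group left with 1 adds none. Chosen after seeing the data were a fit with the beta-actin 3'/5' ratio as a covariate, a fit without the 2 day 12 arrays that correlated least with their groups (WT replicate 1 and SCID replicate 2), and a fit without the 4 arrays with raised skeletal muscle transcripts (WT day 4 replicates 1 and 3, SCID day 4 replicate 3, SCID day 8 replicate 3). This last fit leaves 1 WT day 4 array. Each contrast was also fitted to other splits of the same arrays. Ratios of control probe sets were compared with exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.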

Results

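Whole-lung RNA was measured on Affymetrix Mouse430_2 arrays in male BALB/c mice, 8 weeks old. WT mice and SCID mice, which lack mature B and T cells through a mutation of the DNA repair kinase gene Prkdc, were studied. Mice were uninfected or had received 500 infective larvae (L3) of Nippostrongylus brasiliensis under the skin. This rodent nematode passes through the lung in the first days on its way to the gut. Lungs were taken 2, 3, 4, 8 and 12 days after infection, which with the uninfected mice gave 6 conditions per strain, 12 groups and 36 arrays, 3 per group. The values are array signals (intensity), and the number of arrays limits their precision. Array medians lay between 155.6 and 200.7, and 57.4% to 65.1% of the probe sets of an array reached the filter signal of 109.1. Within a group, log2 signals of 2 arrays correlated across probe sets with r of 0.919 to 0.9667. In all, 14970 genes were tested. Changes below are log2 differences of group means with the standard error of limma (±), n = 3 arrays in each group. A change depends in part on the pseudocount of 16 where a group lies below the filter signal. Where a group averaged under 16, its signal was not separated from background and the change has no measured size, so it is given with signals and its range over the alternatives.

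The uninfected strains were compared first, to see what the missing lymphocytes and any other difference between the strains mean for the lung before infection. Immunoglobulin and B cell genes were among the largest differences. The antibody segment Ighv14-2 was lower in SCID mice, with a background signal of 6.87 ± 3.10 (SD) against 1236 ± 107 (SD) in WT mice (-6.87 to -4.20 over the alternatives). Igkv8-30 differed by -5.25 ± 0.47, the IgA heavy chain gene Igha by -4.73 ± 0.39, and Jchain, which joins antibody units, by -3.45 ± 0.38. Of the 17 B cell genes tested, 11 were lower and none higher (14 adjusted over the list alone, camera adjusted p = 3.87e-49). Among them were Pou2af1 (-3.49 ± 0.34), the antigen receptor subunit gene Cd79a (-3.39 ± 0.40) and Ms4a1 (-2.97 ± 0.38). The T cell receptor subunit gene Cd3d was lower by -3.38 ± 0.43, Ccr7 by -2.76 ± 0.35 and Cd3e by -2.21 ± 0.51. In the T cell list 5 of 23 genes were lower (11 adjusted over the list alone, camera adjusted p = 7.23e-16). In the plasma cell and immunoglobulin list 5 of 12 were lower (5 adjusted over the list alone, camera adjusted p = 3.13e-10), with Ighm at -2.11 ± 0.48. These 3 list calls held with an estimated correlation. Lower in SCID mice too was the antitrypsin gene Serpina1b, with 7.03 ± 2.08 (SD) against 1017 ± 725 (SD) in WT mice (-6.32 to -3.73 over the alternatives). Higher were Tmem45a, from a background signal in WT mice of 13.6 (2.37 to 4.32 over the alternatives), Zfp979 (2.69 ± 0.43), the polo-like kinase gene Plk2 (1.92 ± 0.17), the clock repressor gene Cry1 (1.48 ± 0.23), Zfp386 (1.20 ± 0.14) and Myd88, an adaptor of Toll-like receptors (0.93 ± 0.17). The clock repressor gene Nr1d1 was lower by -1.19 ± 0.21. The Prkdc probe set gave -0.16 ± 0.21 (adjusted p = 1). Limma called 82 genes, 12 higher and 70 lower in SCID mice, of which 7 and 54 differed at least 2-fold. Array weights raised the count to 197, and it was 54, 52 and 53 without WT uninfected replicate 1, WT uninfected replicate 2 or SCID uninfected replicate 2. The calls of Cd3e and Ighm were lost on leaving out any 1 of 5 of the 6 arrays, and that of Myd88 without SCID uninfected replicate 2. In these fits Cd3e stayed between -2.391 and -1.995 and Ighm between -2.256 and -1.988. Cd3e and Ighm also lost their calls without a trend in the variance. Averaging the probe sets of a gene ended the calls of Plk2 (0.89, adjusted p = 0.186) and Ighm (-0.93, adjusted p = 0.186), and with a pseudocount of 64 Zfp979 differed by 1.67.

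At day 2 in WT mice the genes that rose included members of the alternative activation, acute inflammation and cell cycle lists. Retnla, a secreted product of alternatively activated macrophages and airway epithelium, rose 20.1-fold (4.33 ± 0.38, adjusted p = 7.3e-09), and the chitinase-like protein gene Chil3 rose by 1.74 ± 0.27. The acute phase gene Saa3 rose by 3.46 ± 0.61 and the protease inhibitor gene Timp1 by 2.87 ± 0.53. The siderophore-binding lipocalin gene Lcn2 rose by 2.13 ± 0.35, the neutrophil chemokine gene Cxcl5 by 2.04 ± 0.42 and Il1b by 1.14 ± 0.26. In the acute inflammation list 4 of 20 genes rose (11 adjusted over the list alone, camera adjusted p = 3.13e-10), a call that held with an estimated correlation. Of the 29 cell cycle genes 21 rose (25 adjusted over the list alone, camera adjusted p = 5.91e-30, adjusted p = 0.0688 with an estimated correlation). The matrix and repair list had 6 of 19 genes higher (11 adjusted over the list alone, camera adjusted p = 1.07e-09, adjusted p = 0.143 with an estimated correlation). The matrix glycoprotein genes Tnc and Thbs1 rose by 1.84 ± 0.35 and 1.57 ± 0.25. Alternative activation genes rose in 4 of 17 cases (8 adjusted over the list alone, camera adjusted p = 8.34e-09, adjusted p = 0.115 with an estimated correlation). Clca1, a secreted product of goblet cells, rose from a background signal of 12.9 ± 14.4 (SD) to 1890 ± 2620 (SD) (2.75 to 6.20 over the alternatives). The retinaldehyde dehydrogenase gene Aldh1a3 rose from a background signal of 6.3 (1.80 to 4.18 over the alternatives), and the alarmin gene Il33 rose by 0.82 ± 0.20. B cell genes fell in 8 of 17 cases (13 adjusted over the list alone, camera adjusted p = 1.29e-11, adjusted p = 0.0804 with an estimated correlation), with H2-Ob at -1.72 ± 0.32 and Cd79a at -1.76 ± 0.40. In the circadian clock list 2 genes rose and 5 fell of 12 (4 and 6 adjusted over the list alone, camera adjusted p = 0.00187, adjusted p = 0.0846 with an estimated correlation). The clock output gene Dbp fell by 4.54 ± 0.38, the repressor genes Nr1d2 and Nr1d1 by 2.82 ± 0.22 and 2.77 ± 0.21, and Npas2, of the activating arm, rose by 3.20 ± 0.32. The 3'/5' signal ratio of beta-actin, a measure of RNA quality, was 1.21 ± 0.03 (SD) against 1.41 ± 0.07 (SD) in uninfected WT mice (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). Limma called 504 genes, 321 higher and 183 lower, 122 and 39 of them at least 2-fold, and with median centring 418 were higher and 95 lower. The count was 957 with array weights, 292 with the beta-actin ratio as a covariate, 196, 221 and 275 without uninfected replicate 1, 2 or 3, and 229 and 164 without day 2 replicate 1 or 3. Leaving out single arrays ended the calls of Aldh1a3 and Cxcl5 (day 2 replicate 3), Il1b (uninfected replicates 1 and 3, day 2 replicate 3), Cd79a and Il33 (4 of the 6 arrays each) and Clca1 (5 of the 6). Il1b also lost its call with the covariate, and with a pseudocount of 64 Cxcl5 rose by 1.35. Clca1 lost its call with that pseudocount, with no filter, without a trend and with probe sets averaged.

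**Figure D1:**
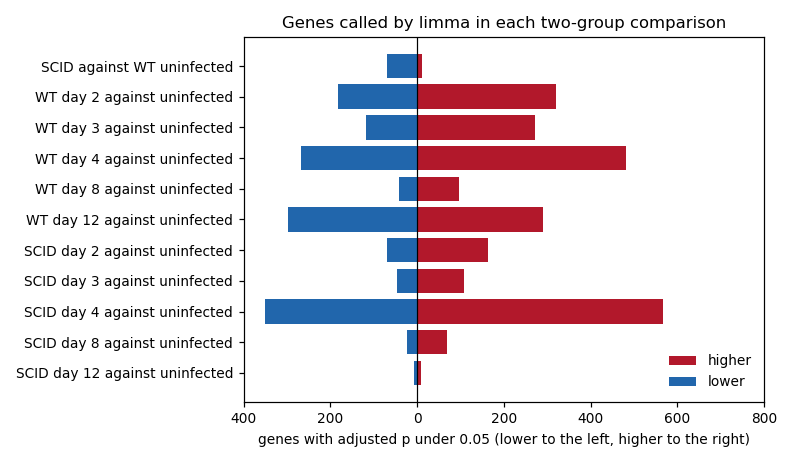
Genes called by limma in each two-group comparison, as horizontal bars from 0: genes higher to the right, genes lower to the left, at an adjusted p under 0.05. WT mice had 751 calls at day 4, 138 at day 8 and 587 at day 12, and SCID mice 920, 92 and 16.

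At day 3 the genes that rose in WT mice included members of the cell cycle, haem and iron, and macrophage lists. The mitotic kinase gene Cdk1 rose by 3.67 ± 0.48, the mitotic regulator genes Birc5 and Bub1b by 3.43 ± 0.43 and 3.26 ± 0.51, and the ubiquitin-conjugating enzyme gene Ube2c by 2.84 ± 0.43. In the cell cycle list 21 of 29 genes rose (26 adjusted over the list alone, camera adjusted p = 5.84e-45), which held with an estimated correlation. Hmox1, the haem-degrading oxygenase gene, rose 13.2-fold (3.72 ± 0.36, adjusted p = 6.5e-08) and the macrophage scavenger receptor gene Marco by 3.62 ± 0.57. The haem and iron list had 3 genes higher and 1 lower of 15 (5 and 1 adjusted over the list alone, camera adjusted p = 0.000103, adjusted p = 0.158 with an estimated correlation). The fall was that of the transferrin receptor gene Tfrc (-0.72 ± 0.13). Macrophage and monocyte genes rose in 3 of 17 cases (7 adjusted over the list alone, camera adjusted p = 4.45e-09, adjusted p = 0.143 with an estimated correlation). Matrix and repair genes rose in 7 of 19 cases (10 adjusted over the list alone, camera adjusted p = 6.28e-11, adjusted p = 0.113 with an estimated correlation). Retnla rose by 4.22 ± 0.38, Chil3 by 1.38 ± 0.27, Il33 by 0.76 ± 0.20 and the lectin receptor gene Clec4e by 1.94 ± 0.44. In the alternative activation list 4 of 17 rose (5 adjusted over the list alone, camera adjusted p = 4.11e-06, adjusted p = 0.211 with an estimated correlation). B cell genes fell in 7 of 17 cases (12 adjusted over the list alone, camera adjusted p = 2.66e-12, adjusted p = 0.0778 with an estimated correlation), with Ms4a1 at -1.42 ± 0.38. The T cell transcription factor gene Lef1 fell by 1.06 ± 0.27. Of 12 clock genes 2 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.000105), a call that held with an estimated correlation. Dbp fell by 4.57 ± 0.38, Nr1d1 by 3.48 ± 0.21 and Nr1d2 by 3.01 ± 0.22, and Npas2 rose by 3.22 ± 0.32. The beta-actin 3'/5' ratio was 1.25 ± 0.06 (SD) against 1.41 ± 0.07 (SD) in uninfected WT mice (exact permutation test, two-sided p = 0.1, the smallest possible). Limma called 390 genes, 273 higher and 117 lower, 115 and 30 of them at least 2-fold, and with median centring 318 were higher and 70 lower. The count was 888 with array weights, 778 in a fit to the compared groups alone, 172, 197 and 248 without uninfected replicate 1, 2 or 3, and 235, 197 and 193 without day 3 replicate 1, 2 or 3. Without single arrays the calls of Ms4a1 and Il33 (6 of 6 arrays), Lef1 (5 of 6) and Clec4e (uninfected replicates 1 and 2, day 3 replicate 3) were lost. Averaging probe sets ended those of Tfrc (adjusted p = 0.281), Lef1 (-0.61) and Ms4a1, and with a pseudocount of 64 Clec4e rose by 1.11. The fit without a trend ended the calls of Il33 and Ms4a1, and the fit to the compared groups alone that of Clec4e.

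Day 4 in WT mice brought more matrix and macrophage genes past the test. Marco rose by 4.23 ± 0.57, Hmox1 by 3.57 ± 0.36, the elastin gene Eln by 2.57 ± 0.28 and the lysosomal glycoprotein gene Gpnmb by 2.08 ± 0.23. The iron exporter gene Slc40a1 rose by 1.56 ± 0.21 and Cd68 by 1.53 ± 0.21. In the matrix and repair list 11 of 19 genes rose (15 adjusted over the list alone, camera adjusted p = 1.83e-13, adjusted p = 0.0804 with an estimated correlation). Among macrophage and monocyte genes 5 of 17 rose (13 adjusted over the list alone, camera adjusted p = 8.2e-11, adjusted p = 0.105 with an estimated correlation). Cell cycle genes rose in 16 of 29 cases (22 adjusted over the list alone, camera adjusted p = 8.72e-23, adjusted p = 0.102 with an estimated correlation). Haem and iron genes rose in 6 cases and fell in 1 of 15 (8 and 2 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.107 with an estimated correlation). Retnla rose by 4.21 ± 0.38, Chil3 by 1.29 ± 0.27 and the lectin receptor gene Clec4d by 1.80 ± 0.24. Of 13 alveolar type 2 cell genes 4 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 9.82e-07, adjusted p = 0.172 with an estimated correlation). The surfactant protein gene Sftpd rose by 0.76 ± 0.16 and the desaturase gene Scd1 by 0.89 ± 0.19, and the transcription factor gene Etv5 fell by 0.61 ± 0.11. B cell genes fell in 7 of 17 cases (9 adjusted over the list alone, camera adjusted p = 1.03e-07, adjusted p = 0.158 with an estimated correlation). The NK cell receptor gene Klrd1 fell by 1.02 ± 0.20 and the stem cell factor receptor gene Kit fell by 0.88 ± 0.19. Of 12 clock genes 3 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.00707, adjusted p = 0.127 with an estimated correlation), and Dbp fell by 4.63 ± 0.38. Skeletal muscle genes stood high in day 4 replicates 1 and 3: the muscle actin gene Acta1 gave 17950 and 8020 there and 156.5 in replicate 2. The muscle myosin gene Myh1 (4.22 ± 1.19) and the troponin gene Tnni2 (from a background signal of 8.8, 0.86 to 5.38 over the alternatives) were the 2 of 10 muscle list members called (6 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.353 with an estimated correlation). Limma called 751 genes, 482 higher and 269 lower, 128 and 40 of them at least 2-fold, and with median centring 753 were higher and 162 lower. The count was 200 in a fit to the compared groups alone, 311, 407 and 481 without uninfected replicate 1, 2 or 3, and 350 without day 4 replicate 1. Without the 4 arrays with raised muscle signal 1 array is left for day 4, and its spread comes wholly from other groups. In that fit Myh1 rose by only 0.56 and Tnni2 by 0.86, and neither was called, so the size of these 2 rises rested on the arrays with raised muscle signal. Chil3 (1.14 there), Etv5, Scd1, Sftpd (0.45), Klrd1 and Kit lost their calls too, losses that cannot be assigned to the muscle signal or to the single array. Sftpd and Kit (-0.58) lost their calls also without day 4 replicate 1 alone, and Myh1 and Tnni2 without 5 of the 6 arrays. The fit to the compared groups alone ended the calls of Sftpd, Kit, Myh1 and Tnni2, array weights those of Myh1 and Tnni2, and averaged probe sets that of Scd1, while Sftpd rose by 0.45 with quantile normalization.

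**Figure D2:**
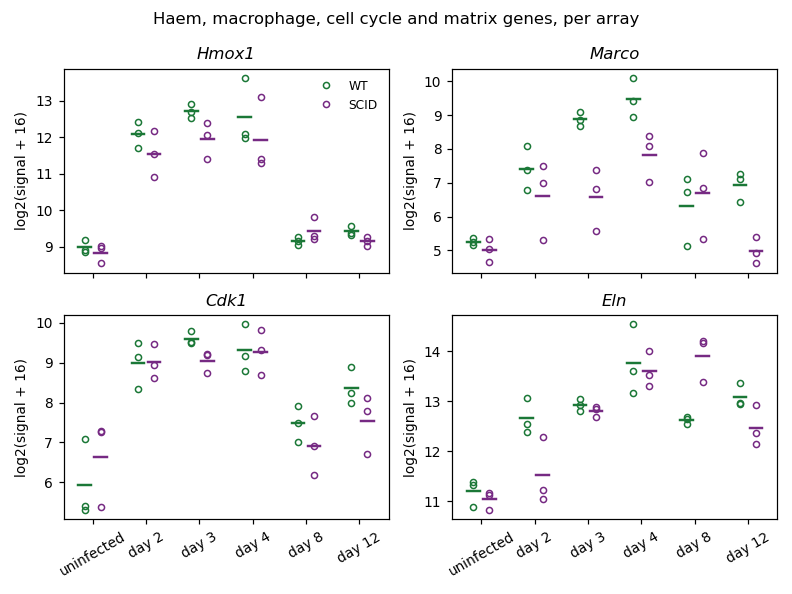
Signal of Hmox1, Marco, Cdk1 and Eln in the uninfected mice and on each of the 5 days after infection, as log2(signal + 16): each circle is 1 array, bars are the means of 3 arrays, WT green and SCID purple. Hmox1 averaged 494.6 in uninfected WT mice, 6703 at day 3 and 554.3 at day 8.

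The largest rises at day 8 in WT mice included goblet cell and alternative activation genes. Clca1 rose from a background signal of 12.9 ± 14.4 (SD) to 7860 ± 5140 (SD) (4.26 to 8.87 over the alternatives, adjusted p = 0.0036). The RNase gene Rnase2a, of a family that eosinophils and macrophages express, rose by 4.68 ± 0.69, Retnla by 4.60 ± 0.38 and the transcription factor gene Zbtb16 by 3.90 ± 0.60. The anion exchanger gene Slc26a4 rose by 3.20 ± 0.52, the IgM heavy chain gene Ighm by 2.30 ± 0.48 and Chil3 by 2.10 ± 0.27. Alternative activation genes rose in 5 of 17 cases (8 adjusted over the list alone, camera adjusted p = 4.64e-16). Type 2 chemokine genes rose in 2 of 7 (4 adjusted over the list alone, camera adjusted p = 9.4e-08) and mast cell and basophil genes in 1 of 11 (2 adjusted over the list alone, camera adjusted p = 2.76e-05). These 3 list calls held with an estimated correlation. In the goblet cell and mucus list 3 of 15 genes rose (9 adjusted over the list alone, camera adjusted p = 2.32e-12, adjusted p = 0.0778 with an estimated correlation). Matrix and repair genes rose in 3 of 19 cases (5 adjusted over the list alone, camera adjusted p = 2.41e-08, adjusted p = 0.176 with an estimated correlation). No cell cycle gene passed (camera adjusted p = 0.00542, adjusted p = 0.732 with an estimated correlation). Dbp fell by 4.64 ± 0.38, the homeobox gene Emx1 by 2.07 ± 0.36 and Ighv14-2 by 2.09 ± 0.45. Clock genes rose in 3 and fell in 5 of 12 cases (5 and 6 adjusted over the list alone, camera adjusted p = 0.0706, not passed). Limma called 138 genes, 96 higher and 42 lower, 35 and 19 of them at least 2-fold. The count was 227 with median centring (192 higher and 35 lower), 423 with array weights, 211 in a fit to the compared groups alone, 55, 85 and 67 without uninfected replicate 1, 2 or 3, and 88 and 51 without day 8 replicate 1 or 2. The calls of Ighm (uninfected replicate 3, day 8 replicates 1 and 2) and Ighv14-2 (each uninfected replicate, day 8 replicate 3) were lost without single arrays. That of Ighm was lost also in a fit to the compared groups alone and with probe sets averaged, where the rise was 0.53 (adjusted p = 0.477), and that of Ighv14-2 with a pseudocount of 4. With a pseudocount of 64 Emx1 fell by 1.30.

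At day 12 the genes that rose in WT mice included alternative activation, chemokine, goblet cell and antibody genes. Clca1 rose from a background signal of 12.9 ± 14.4 (SD) to 10720 ± 10600 (SD) (4.50 to 9.07 over the alternatives). Rnase2a rose by 5.35 ± 0.69, Retnla 29.5-fold (4.88 ± 0.38, adjusted p = 1.3e-09), Slc26a4 by 4.36 ± 0.52 and the monocyte and eosinophil chemokine gene Ccl8 by 3.88 ± 0.59. The macrophage elastase gene Mmp12 rose by 2.65 ± 0.26 and Chil3 by 2.60 ± 0.27. In all, 9 of 17 alternative activation genes rose (12 and 1 fall adjusted over the list alone, camera adjusted p = 4.7e-13, adjusted p = 0.0619 with an estimated correlation). Of 7 type 2 chemokine genes 5 rose (6 adjusted over the list alone, camera adjusted p = 1.5e-08, held with an estimated correlation). Ccl17 rose by 2.10 ± 0.36, Ccl24 by 2.04 ± 0.53 and the eotaxin gene Ccl11 by 1.90 ± 0.43. Macrophage and monocyte genes rose in 7 of 17 cases (14 adjusted over the list alone, camera adjusted p = 5.69e-10, adjusted p = 0.115 with an estimated correlation), with the complement gene C1qc at 1.44 ± 0.32. The goblet cell and mucus list had 4 of 15 genes higher (8 adjusted over the list alone, camera adjusted p = 4.58e-09, adjusted p = 0.124 with an estimated correlation), among them the antibody transporter gene Pigr (2.31 ± 0.26). Plasma cell and immunoglobulin genes rose in 3 of 12 cases (3 adjusted over the list alone, camera adjusted p = 0.0048, adjusted p = 0.0846 with an estimated correlation). Ighm rose by 3.32 ± 0.48, Jchain by 1.87 ± 0.38 and Iglv1 by 1.61 ± 0.46. Basophil and mast cell genes rose in 3 of 11 (4 adjusted over the list alone, camera adjusted p = 0.00361, adjusted p = 0.0804 with an estimated correlation). The protease genes rose, Mcpt8 by 2.67 ± 0.66 and Mcpt2 by 2.18 ± 0.59, and the histamine-forming enzyme gene Hdc by 1.02 ± 0.17. Dendritic cell and MHC class II genes rose in 2 of 14 (6 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.303 with an estimated correlation), Itgax by 1.04 ± 0.15 and Cd83 by 0.90 ± 0.23. The NK receptor gene Klrk1 fell by 1.26 ± 0.25 and the endothelial receptor gene Tek by 0.58 ± 0.11. The beta-actin 3'/5' ratio was 1.85 ± 0.10 (SD) against 1.41 ± 0.07 (SD) in uninfected WT mice (exact permutation test, two-sided p = 0.1, the smallest possible). Limma called 587 genes, 290 higher and 297 lower, 87 and 30 of them at least 2-fold. With the beta-actin ratio as a covariate 7 were called, among the genes named here only Retnla, Chil3, Mmp12, Pigr and Slc26a4, and the count was 899 with array weights and 300 in a fit to the compared groups alone. It was 189, 189 and 248 without uninfected replicate 1, 2 or 3 and 253 and 362 without day 12 replicate 2 or 3. Single arrays ended the calls of Ccl24, Mcpt8, Mcpt2 and Iglv1 (4 of 6 arrays each), Ccl11 (3 of 6), C1qc (uninfected replicate 1, day 12 replicate 3) and Cd83 (5 of 6). The fit to the compared groups alone ended those of Klrk1, Mcpt2 and Iglv1, and Iglv1 lost its call also with a pseudocount of 4, the stricter filter, median centring and averaged probe sets (1.01). With averaged probe sets Ighm rose by 1.67, and with a pseudocount of 64 Ccl24 rose by 1.34.

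**Figure D3:**
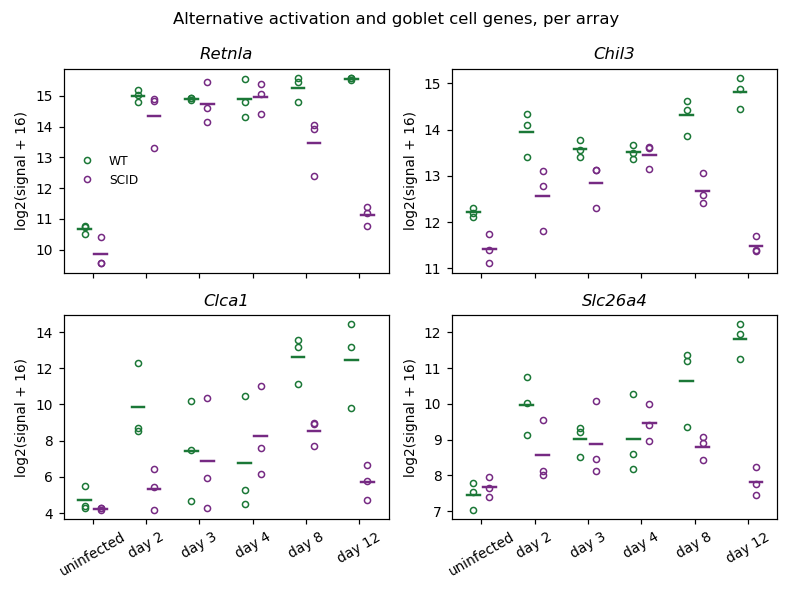
Signal of Retnla, Chil3, Clca1 and Slc26a4 in the uninfected mice and on each of the 5 days after infection, as log2(signal + 16): each circle is 1 array, bars are the means of 3 arrays, WT green and SCID purple. Retnla averaged 48180 in WT mice and 2239 in SCID mice at day 12.

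In SCID mice at day 2 Retnla rose by 4.50 ± 0.38 (22.6-fold, adjusted p = 1.1e-08), Hmox1 by 2.70 ± 0.36 and Timp1 by 2.63 ± 0.53. The thymidine kinase gene Tk1 rose by 2.56 ± 0.49, Ube2c by 2.54 ± 0.43, Saa3 by 2.44 ± 0.61 and Tnc by 1.79 ± 0.35. The neutrophil genes S100a9 and S100a8, which encode the calprotectin subunits, rose by 1.49 ± 0.29 and 1.27 ± 0.32. In all, 5 of 17 neutrophil genes rose (8 adjusted over the list alone, camera adjusted p = 9.4e-08, adjusted p = 0.107 with an estimated correlation). Cell cycle genes rose in 13 of 29 cases (25 adjusted over the list alone, camera adjusted p = 1.21e-32, adjusted p = 0.0553 with an estimated correlation). The acute inflammation list had 3 of 20 higher (5 and 1 fall adjusted over the list alone, camera adjusted p = 0.000163, adjusted p = 0.208 with an estimated correlation), with Il1b at 1.28 ± 0.26. Alternative activation genes rose in 2 of 17 cases (4 adjusted over the list alone, camera adjusted p = 4.81e-05, adjusted p = 0.287 with an estimated correlation). Chil3 rose by 1.16 ± 0.27, Il33 by 0.94 ± 0.20 and Manf, a product of the unfolded protein response, by 0.69 ± 0.14. The carboxylesterase gene Ces1g fell by 1.73 ± 0.31, Vpreb3 by 1.6 ± 0.28, the glutathione transferase gene Gsta2 by 1.44 ± 0.29 and Klrd1 by 0.78 ± 0.20. The beta-actin 3'/5' ratio was 1.25 ± 0.08 (SD) against 1.38 ± 0.03 (SD) in uninfected SCID mice (exact permutation test, two-sided p = 0.1, the smallest possible). Limma called 233 genes, 164 higher and 69 lower, 62 and 10 of them at least 2-fold, and with median centring 189 were higher and 41 lower. The count was 31 in a fit to the compared groups alone, a fit that left only Retnla, Hmox1 and S100a9 of the genes named here. It was 108, 98 and 151 without uninfected replicate 1, 2 or 3 and 385 and 57 without day 2 replicate 2 or 3. Single arrays ended the calls of Gsta2, Timp1 and Tnc (day 2 replicate 3), Tk1 (uninfected replicate 1), Il1b (uninfected replicate 2), Manf (uninfected replicate 1, day 2 replicate 3), Il33 (3 of 6) and Chil3, S100a8, Saa3 and Klrd1 (4 of 6 each). The fit without a trend ended those of S100a8 and Saa3, the beta-actin covariate those of S100a8 and Klrd1, and Klrd1 lost its call also with no filter, quantile normalization, median centring and without the 4 muscle arrays.

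At day 3 in SCID mice Retnla rose by 4.90 ± 0.38 and Hmox1 by 3.11 ± 0.36. The kinetochore gene Nuf2 rose by 2.63 ± 0.44, Ube2c by 2.63 ± 0.43 and Tk1 by 2.49 ± 0.49. Of 29 cell cycle genes 13 rose (24 adjusted over the list alone, camera adjusted p = 4.88e-31, adjusted p = 0.0619 with an estimated correlation). In the matrix and repair list 4 rose and 1 fell of 19 (11 and 1 adjusted over the list alone, camera adjusted p = 1.23e-08, adjusted p = 0.169 with an estimated correlation). Chil3 rose by 1.44 ± 0.27 and Il33 by 0.84 ± 0.20. Falls included Ces1g (-1.75 ± 0.31), the clock gene Per2 (-1.72 ± 0.38) and the club cell glutathione transferase gene Gsta3 (-1.54 ± 0.29). Club cell genes fell in 2 of 11 cases (2 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.355 with an estimated correlation). Limma called 155 genes, 109 higher and 46 lower, 47 and 6 of them at least 2-fold, and with median centring 107 were higher and 28 lower. The count was 92 without a trend in the variance, 383 with array weights, 45 and 63 without uninfected replicate 1 or 2, and 71 and 69 without day 3 replicate 1 or 2. Without single arrays the calls of Gsta3 (day 3 replicate 2), Chil3 (uninfected replicate 1), Tk1 (uninfected replicate 1, day 3 replicate 1), Per2 (4 of 6) and Il33 (5 of 6) were lost. A fit to the compared groups alone ended those of Nuf2, Tk1 and Il33, the fit without a trend that of Il33, and averaged probe sets that of Per2 (-1.10).

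At day 4 in SCID mice Retnla rose 34.6-fold (5.11 ± 0.38, adjusted p = 4.1e-10), Hmox1 by 3.09 ± 0.36 and the cyclin gene Ccna1 by 2.84 ± 0.46. Marco rose by 2.82 ± 0.57, Cdk1 by 2.64 ± 0.48 and the acyl-CoA oxidase-like gene Acoxl from a background signal of 12.2 (1.66 to 3.49 over the alternatives). Of 17 alternative activation genes 7 rose (10 adjusted over the list alone, camera adjusted p = 9.5e-12, adjusted p = 0.0778 with an estimated correlation). The arginase gene Arg1 rose by 2.59 ± 0.73, Chil3 by 2.05 ± 0.27 and the lectin receptor gene Clec7a by 1.15 ± 0.18. Cell cycle genes rose in 19 of 29 cases (23 adjusted over the list alone, camera adjusted p = 7.8e-22, adjusted p = 0.105 with an estimated correlation). Matrix and repair genes rose in 12 of 19 (14 and 1 fall adjusted over the list alone, camera adjusted p = 2.94e-13, adjusted p = 0.083 with an estimated correlation), the growth factor gene Igf1 by 1.41 ± 0.26. Macrophage genes rose in 4 of 17 (6 and 1 fall adjusted over the list alone, camera adjusted p = 4.19e-06, adjusted p = 0.256 with an estimated correlation), Gpnmb by 2.37 ± 0.23 and Cd68 by 1.42 ± 0.21. In the alveolar type 2 cell list 8 of 13 rose (11 and 1 fall adjusted over the list alone, camera adjusted p = 4.58e-09, adjusted p = 0.105 with an estimated correlation), including the lipid synthesis genes Scd1 (1.21 ± 0.19) and Fasn (1.16 ± 0.21). Slc40a1 rose by 1.25 ± 0.21, Hdc by 1.11 ± 0.17, Slc26a4 by 1.79 ± 0.52, Il33 by 0.98 ± 0.20 and the cilium gene Rsph1 by 1.01 ± 0.21. The sulfate transporter gene Slc13a4 fell by 2.17 ± 0.42, Ces1g by 2.12 ± 0.31 and Vpreb3 by 1.97 ± 0.28. The immediate early gene Egr1 fell by 1.61 ± 0.37, the club cell monooxygenase gene Fmo2 by 1.08 ± 0.21 and Tek by 0.59 ± 0.11. Club cell genes fell in 3 of 11 cases (1 rise and 5 falls adjusted over the list alone, camera adjusted p = 0.107, not passed). Day 4 replicate 3 held raised muscle signal (Acta1 6735), and replicate 2 held liver transcripts, with the albumin gene Alb at 14122. Limma called 920 genes, 568 higher and 352 lower, 149 and 44 of them at least 2-fold, and with median centring 797 were higher and 206 lower (482 and 386 with quantile normalization). The count was 336 in a fit to the compared groups alone, 380 and 574 without uninfected replicate 1 or 2, and 319 without day 4 replicate 1. Without single arrays the calls of Arg1 and Slc26a4 (5 of 6 each), Egr1 (day 4 replicate 2) and Il33 (day 4 replicate 1) were lost. The fit to the compared groups alone ended those of Arg1 and Fasn, and the fit without a trend that of Slc26a4. With a pseudocount of 64 Marco rose by 1.80.

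At day 8 in SCID mice Retnla rose by 3.62 ± 0.38, Eln by 2.87 ± 0.28, the matrix protein gene Spon2 by 2.07 ± 0.25, Ccl17 by 1.84 ± 0.36 and Chil3 by 1.27 ± 0.27. Acoxl rose from a background signal of 12.2 (1.52 to 3.29 over the alternatives). Alveolar type 2 cell genes rose in 3 of 13 cases (10 adjusted over the list alone, camera adjusted p = 9.23e-14), which held with an estimated correlation. In the matrix and repair list 4 of 19 rose (12 and 1 fall adjusted over the list alone, camera adjusted p = 1.15e-13, adjusted p = 0.0804 with an estimated correlation). In the alternative activation list 4 of 17 rose (5 adjusted over the list alone, camera adjusted p = 8.63e-07, adjusted p = 0.179 with an estimated correlation). Clock genes rose in 4 and fell in 3 of 12 cases (4 and 6 adjusted over the list alone, camera adjusted p = 0.26, not passed). The activator genes Arntl and Npas2 rose by 1.73 ± 0.21 and 1.57 ± 0.32, and Per2 and Cry1 fell by 2.16 ± 0.38 and 1.73 ± 0.23. Ces1g fell by 1.52 ± 0.31, and Clca1, with 385.5 ± 164 (SD) against a background signal of 3.07 ± 0.81 (SD), was not called (adjusted p = 0.24). Day 8 replicate 3 held raised muscle signal (Acta1 1849). Limma called 92 genes, 68 higher and 24 lower, 26 and 6 of them at least 2-fold. The count was 61 without a trend in the variance, 264 with array weights, 31 and 46 without uninfected replicate 1 or 2, and 26 and 35 without day 8 replicate 1 or 2. Single arrays ended the calls of Per2 (day 8 replicate 1), Ccl17 (uninfected replicate 3, day 8 replicate 1), Chil3 (uninfected and day 8 replicates 1 and 2), Npas2 and Ces1g (3 of 6 each). The fit to the compared groups alone ended that of Npas2, and the fit without the 4 muscle arrays that of Ces1g. With probe sets averaged Spon2 rose by 1.10 and Arntl by 0.84.

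Few genes were called in SCID mice at day 12. Eln was higher by 1.43 ± 0.28, Spon2 by 1.39 ± 0.25, Nr1d1 by 1.35 ± 0.21, the calcium channel gene Cacna1d by 1.02 ± 0.22 and the clock gene Ciart by 0.91 ± 0.19. Cry1 fell by 1.77 ± 0.23, Lonrf3 by 0.91 ± 0.16 and the interferon-induced membrane protein gene Ifitm1 by 0.81 ± 0.16. Retnla gave 1.27 ± 0.38 (adjusted p = 0.31) and Chil3 0.08 ± 0.27 (adjusted p = 0.98). No member of the alveolar type 2 cell list passed (1 adjusted over the list alone), with camera adjusted p = 9.03e-06 upward and adjusted p = 0.215 with an estimated correlation. Limma called 16 genes, 9 higher and 7 lower, 4 and 1 of them at least 2-fold, and with median centring 7 were higher and 4 lower. The count was 8 without a trend in the variance, 4 with probe sets averaged, 9 in a fit to the compared groups alone, 10 with the beta-actin ratio as a covariate, 9 without WT replicate 1 and SCID replicate 2 of day 12, and 10 without the 4 muscle arrays. It was 8, 5 and 7 without uninfected replicate 1, 2 or 3 and 6, 7 and 29 without day 12 replicate 1, 2 or 3. Of the genes named as called only Cry1 and Nr1d1 kept their call under all 20 alternatives, and with probe sets averaged Spon2 gave 0.62 and Lonrf3 -0.57.

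The overlap of the strains asks how much of the response arises in mice without B and T cells. The strains have their own uninfected mice, so the lists share no control arrays. The chance counts below take the calls of the strains as independent. Both strains share 1 estimate of the spread of each gene, so these chance counts may be too low. At day 2, 109 genes rose and 25 fell in both strains, where 3.52 and 0.84 would meet by chance, and Retnla, Chil3, Timp1 and Saa3 were among the rises. At day 3, 75 rose and 17 fell in both (1.99 and 0.36 by chance), and at day 4, 269 and 97 (18.29 and 6.33 by chance), with Hmox1, Marco, Eln and Gpnmb among the rises at day 4. At day 8, 12 rose and 5 fell (0.44 and 0.07 by chance), among them Retnla, Chil3, Ccl17, Eln and Arntl. At day 12 the shared genes were Eln, Cxcl15, Nrcam, Cys1 and Adh5 (3 rises and 2 falls, 0.17 and 0.14 by chance), named after their values were seen. Nr1d1 was called in opposite directions at days 3, 4 and 8, and Lonrf3 at day 4. Of the genes called in WT mice, 478 of 504 at day 2, 358 of 390 at day 3, 720 of 751 at day 4, 109 of 138 at day 8 and 448 of 587 at day 12 had an estimate of the same sign in SCID mice, which is not a test of equal responses. The shared totals of 134, 92, 366, 17 and 5 moved under single arrays to between 35 and 185, 33 and 90, 174 and 391, 7 and 18, and 1 and 6. At day 4 the total was 61 without the 4 muscle arrays, where WT day 4 is 1 array, and at day 12 it was 0 with the beta-actin ratio as a covariate.

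The tests of the response difference ask directly whether the change with infection in SCID mice differed from that in WT mice, as the SCID change minus the WT change. At days 2 to 4 the called genes were clock genes and Lonrf3. Dbp differed by 4.30 ± 0.54, 3.57 ± 0.54 and 3.76 ± 0.54 at days 2, 3 and 4, and Nr1d1 by 3.43 ± 0.30, 4.35 ± 0.30 and 3.04 ± 0.30. Nr1d2 differed by 2.32 ± 0.31 and 2.24 ± 0.31 at days 2 and 3, and Npas2 by -2.83 ± 0.45 at day 2. Cry1 differed by -2.10 ± 0.33 at day 3, and Lonrf3 by -1.27 ± 0.22 and -1.35 ± 0.22 at days 2 and 4. The clock list had 3 genes higher and 1 lower of 12 at day 2 and at day 3 (5 and 2 adjusted over the list alone at both days, camera adjusted p = 4.38e-07 and 2.26e-05), both held with an estimated correlation. At day 4, 2 of 12 were higher (3 and 2 lower adjusted over the list alone, camera adjusted p = 0.00524 upward although the list median was -0.015, adjusted p = 0.115 with an estimated correlation). No B cell gene passed alone at days 2 to 4, but the list's camera adjusted p was 6.79e-10, 1.13e-10 and 1.51e-05, upward (7, 8 and 5 adjusted over the list alone, with 1 lower at day 4). With an estimated correlation it was 0.105, 0.0867 and 0.259 (adjusted p). Uninfected SCID mice already lack most of this signal, so a fall in WT mice alone gives an upward difference, which is no sign of a response in SCID mice. Retnla differed by 0.17 ± 0.54, 0.68 ± 0.54 and 0.90 ± 0.54 at these days (adjusted p = 1 each). Limma called 5 genes at day 2 (3 higher, 2 lower), 4 at day 3 (3 and 1) and 3 at day 4 (2 and 1), against 486, 593 and 665 at an unadjusted p under 0.05. Day 2 gave 9 with array weights, 3 with probe sets averaged and 8 without SCID day 2 replicate 3. Day 3 gave 8 with array weights, and day 4 gave 12 without the 4 muscle arrays (1 array left for WT day 4) and 21 without WT day 4 replicate 1. Lonrf3 lost its day 2 call without WT uninfected replicate 2, SCID uninfected replicate 2, WT day 2 replicate 1 or SCID day 2 replicate 2, and its calls at days 2 and 4 in a fit to the compared groups alone. With probe sets averaged Npas2 (adjusted p = 0.136) and Lonrf3 lost their calls at day 2.

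**Figure D4:**
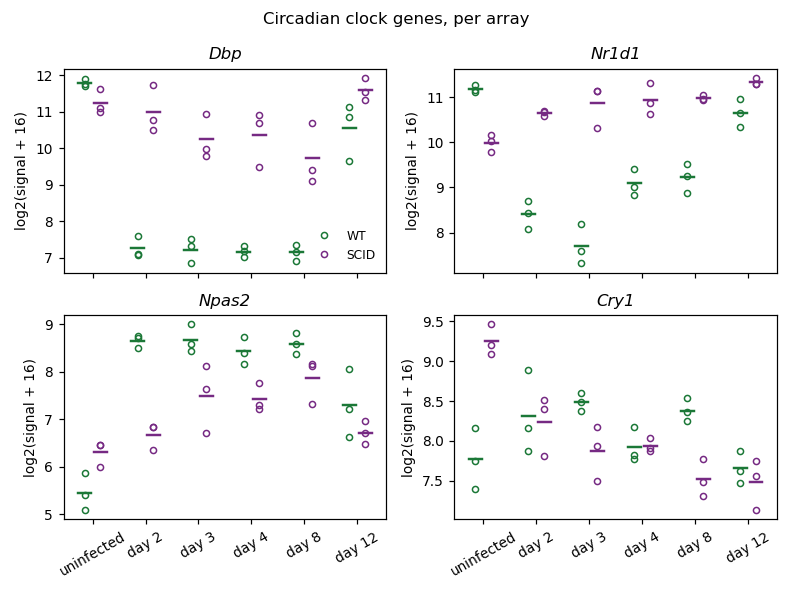
Signal of Dbp, Nr1d1, Npas2 and Cry1 in the uninfected mice and on each of the 5 days after infection, as log2(signal + 16): each circle is 1 array, bars are the means of 3 arrays, WT green and SCID purple. Nr1d1 averaged 2309 in uninfected WT mice and 198.5 at day 3, and 1004 and 1900 in SCID mice.

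At day 8 the strains differed in Nr1d1 (2.95 ± 0.30), Dbp (3.14 ± 0.54), Cry1 (-2.34 ± 0.33), the cell cycle inhibitor gene Cdkn1a (-1.62 ± 0.29), the acidic chitinase gene Chia1 (-1.61 ± 0.27), the crosslinking enzyme gene Loxl1 (1.10 ± 0.17) and Etv5 (0.77 ± 0.15). Mast cell and basophil genes had no member called (2 lower adjusted over the list alone, camera adjusted p = 8.75e-05 downward), a list call that held with an estimated correlation, and Mcpt8 gave -2.95 ± 0.94 (adjusted p = 0.46). No goblet cell gene passed either (1 lower adjusted over the list alone, camera adjusted p = 1.19e-07 downward, adjusted p = 0.166 with an estimated correlation), and Clca1 was not called (adjusted p = 1). At day 12 the change was lower in SCID than in WT mice for 13 genes, among them alternative activation, chemokine and goblet cell genes. Retnla differed by -3.61 ± 0.54 (adjusted p = 0.0006), Ccl8 by -4.94 ± 0.83, Slc26a4 by -4.22 ± 0.74, Pigr by -2.57 ± 0.36, Chil3 by -2.53 ± 0.38 and Mmp12 by -2.52 ± 0.36. Rnase2a differed by -4.94 ± 0.98, Ighm by -3.20 ± 0.68, Ccl11 by -3.10 ± 0.61 and Cxcl5 by -3.0 ± 0.59, and Nr1d1 by 1.89 ± 0.30. In the type 2 chemokine list 2 of 7 were lower (4 adjusted over the list alone, camera adjusted p = 3.02e-08), which held with an estimated correlation. Alternative activation genes were lower in 4 of 17 cases (6 adjusted over the list alone, camera adjusted p = 2.88e-10, adjusted p = 0.0867 with an estimated correlation). Goblet cell and mucus genes were lower in 2 of 15 (9 adjusted over the list alone, camera adjusted p = 1.18e-12, adjusted p = 0.0778 with an estimated correlation). Of 17 macrophage and monocyte genes none was called (9 lower adjusted over the list alone, camera adjusted p = 1.2e-10 downward, adjusted p = 0.105 with an estimated correlation). Limma called 11 genes at day 8 (4 higher, 7 lower, but 6 and 5 with quantile normalization; 804 at an unadjusted p under 0.05) and 17 at day 12 (4 and 13; 1359). Day 8 gave 53 with array weights, 5 without a trend, 7 with probe sets averaged, 29 in a fit to the compared groups alone, and 5 to 7 without WT uninfected replicate 1, any SCID uninfected replicate, WT day 8 replicate 1 or 2 or SCID day 8 replicate 3. Etv5 and Cdkn1a lost their calls without 9 and 4 of the 12 arrays and without a trend, Etv5 with median centring, and both and Loxl1 with probe sets averaged. Day 12 gave 39 with array weights, 26 in a fit to the compared groups alone, 7 with the beta-actin ratio as a covariate, 10 or 11 without any WT uninfected replicate, SCID uninfected replicate 3 or WT day 12 replicate 2 or 3, and 51 without WT day 12 replicate 1. Rnase2a, Ighm, Ccl11 and Cxcl5 lost their calls without 6, 11, 9 and 8 of the 12 arrays. These 4 and Slc26a4 lost them with the covariate. Rnase2a lost its call also with a pseudocount of 4 and without a trend, Ccl11 and Cxcl5 in a fit to the compared groups alone, Cxcl5 with a pseudocount of 64 (-1.82) and without the 2 day 12 arrays, and Ighm under 7 further settings, among them averaged probe sets (-1.58).

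Some genes and lists chosen for this infection gave few or no calls. Il4 was called in no comparison, with WT changes between -0.52 ± 0.31 at day 2 and 0.38 ± 0.31 at day 12. Il5, Il13 and the eosinophil granule gene Prg2 stayed below the filter and were not tested, Il13 with means of 11.2 to 37.9 over the groups. Il5 averaged 7.87 in uninfected WT mice and 70.9 at day 2 (single arrays 4.4 to 10.8 and 38.4 to 124), and Il5ra, also untested, 24.8 in uninfected and 107.7 in day 12 WT mice. In SCID mice Il5 averaged 16.57 uninfected and 56.03 at day 12 (single arrays 7.9 to 31.3 and 27.1 to 76.8). Of the eosinophil list only Siglecf was tested, so the list was not tested; Siglecf gave 1.03 ± 0.28 in SCID mice at day 8 (adjusted p = 0.0943). The club cell gene Scgb1a1, the surfactant gene Sftpc and the mucin gene Muc5ac passed in no comparison, Muc5ac with 1.81 ± 0.62 in WT mice at day 8 (adjusted p = 0.18). The haemoglobin gene Hbb-b1 is read only by a probe set shared with Hbb-bt, Hbb-bs and Hbb-b2, which gave 32460 ± 846 (SD) in uninfected and 45510 ± 1640 (SD) in day 12 WT mice and was not tested. It was as high earlier, with 43970 at day 4 and 44220 at day 8 in WT mice. In SCID mice it gave 32620 uninfected and 43120 at day 4. The type 2 cytokine and receptor list (12 genes) passed camera nowhere (lowest adjusted p = 0.0671), nor did the alveolar type 1 list (10 genes, lowest 0.0593) and the thymus list (5 genes, lowest 0.145). In the type I interferon list 3 of 17 rose in WT mice at day 2 (5 adjusted over the list alone, camera adjusted p = 0.000987, adjusted p = 0.345 with an estimated correlation). Zbp1 rose by 1.38 ± 0.39, a call lost without 5 of the 6 arrays, with no filter, without a trend, with probe sets averaged and with the beta-actin covariate. Ciliated cell genes gave camera adjusted p = 0.000391 downward at day 2 in WT mice (0 fell, 6 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation).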

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

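The tests of the clock genes, of RNA quality and of the lack of lymphocytes were chosen only after the result was seen. So were the liver genes looked at, the arrays left out for muscle signal and the genes compared with and without the covariate. The tests around Ighm and Prkdc and the other splits were chosen before the data were examined. Groups of 3 arrays were not tested for outliers, and what stands here are differences between the strains in the response to infection, each called by limma (SCID change minus WT change, log2, ± SE, n = 3 arrays in each of 4 groups).

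At day 2 the response differed for Dbp (4.30 ± 0.54), Nr1d1 (3.43 ± 0.30), Npas2 (-2.83 ± 0.45), Nr1d2 (2.32 ± 0.31) and Lonrf3 (-1.27 ± 0.22). At day 3 it differed for Nr1d1 (4.35 ± 0.30), Dbp (3.57 ± 0.54), Nr1d2 (2.24 ± 0.31) and Cry1 (-2.10 ± 0.33), and at day 4 for Dbp (3.76 ± 0.54), Nr1d1 (3.04 ± 0.30) and Lonrf3 (-1.35 ± 0.22). Day 8 gave Dbp (3.14 ± 0.54), Nr1d1 (2.95 ± 0.30), Cry1 (-2.34 ± 0.33), Cdkn1a (-1.62 ± 0.29), Chia1 (-1.61 ± 0.27), the Krüppel-like factor gene Klf9 (-1.23 ± 0.25), Lonrf3 (-1.11 ± 0.22), Loxl1 (1.10 ± 0.17), the phosphatidate phosphatase gene Lpin2 (-0.94 ± 0.19), Fam117b (-0.92 ± 0.18) and Etv5 (0.77 ± 0.15). At day 12 the genes with a lower change in SCID mice were Rnase2a (-4.94 ± 0.98), Ccl8 (-4.94 ± 0.83), Slc26a4 (-4.22 ± 0.74), Retnla (-3.61 ± 0.54), Ighm (-3.20 ± 0.68), Ccl11 (-3.10 ± 0.61), Cxcl5 (-3.0 ± 0.59), Nfil3 (-2.70 ± 0.51), Pigr (-2.57 ± 0.36), Chil3 (-2.53 ± 0.38), Mmp12 (-2.52 ± 0.36), Chia1 (-2.21 ± 0.27) and Cry1 (-1.66 ± 0.33). Nr1d1 (1.89 ± 0.30), Mmp11 (1.14 ± 0.24), Gna11 (0.78 ± 0.17) and Sh2b3 (0.64 ± 0.14) had a higher change there. Of 26 alternatives, single arrays left out included, 20 ended the day 12 call of Gna11, 19 that of Ighm, 17 those of Mmp11 and Sh2b3, 11 that of Ccl11 and 9 that of Rnase2a, and 12 of 25 ended that of Cxcl5. At day 8 the calls of Etv5 and Cdkn1a ended in 12 and 6 of 26, at day 2 that of Lonrf3 in 6, and in 1 each those of Npas2 (day 2), Lonrf3 (day 4), Loxl1 (day 8) and Slc26a4 (day 12). The alternatives were not run gene by gene for Nfil3, Klf9, Lpin2 and Fam117b, for Lonrf3 at day 8, or for Chia1 and Cry1 at day 12, and no alternative ended the other calls.

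Other splits of the same arrays show how often so many genes are called without the real grouping. For the response difference the strain labels were shuffled within each condition, and 100 splits were compared, the real one included. At day 2 the real count of 5 was reached by 2 splits, the real one included (highest other 5), and at day 3 the count of 4 by 2 (highest other 7). At day 8 the count of 11 was reached by 1 (highest other 5) and at day 12 the count of 17 by 4. These are shares under 0.05 at these 4 days, not adjusted over the days. The splits also mix strains that differ before infection, so they do not test the response difference alone and cannot exclude chance. One of the other splits at day 12 called 82 genes, and which arrays make it up was not examined. At day 4 the count of 3 was reached by 8 of 100 splits (highest other 7), a share above 0.05. The two-group comparisons have 10 splits each, too few for a share under 0.05, and in each 1 split, the real one, reached its count. These were 82 for the uninfected mice (highest other 0), 504, 390, 751, 138 and 587 for WT days 2, 3, 4, 8 and 12 (highest others 0, 0, 2, 1 and 1), and 233, 155, 920, 92 and 16 for SCID mice (highest others 1, 1, 2, 4 and 1).

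The first pattern is the clock genes of WT mice: Dbp averaged 3531 in uninfected WT mice, 127 to 139 at days 2 to 8 and 1612 at day 12, against 945 to 3137 in infected SCID mice. A change from the uninfected mice alike in both strains is argued against for Dbp, Nr1d1, Nr1d2 and Cry1. Of 48 tests of the response difference over 12 clock members at days 2 to 8, 13 were called by limma. The only call of Npas2 was lost with probe sets averaged (limma adjusted p = 0.136). All days of a strain share its uninfected arrays, so calls of 1 gene at several days are not independent. Cry1 was called in WT mice at none of these days (changes of 0.15 to 0.72). These calls do not decide on an effect of infection alike in both strains. A difference between the uninfected groups, as in harvest time, could give them too. Over all 9 members called in WT mice the SCID change was a median of 0.39 of the WT change (quartiles 0.21 to 0.74), which decided nothing, and the 0.78 (quartiles 0.49 to 1.02) of the 5 members with no called difference is drawn upward by that choice, so for them an effect alike in both strains cannot be told apart from a weaker one. Of the 12 members 11 in WT (Ciart by only -0.04) and 9 in SCID mice followed the order, by opposite phases, that harvest at different times of day would give, the labels state no harvest time, and uninfected SCID mice already differed from WT mice in Cry1 (1.48) and Nr1d1 (-1.19), which enters their response differences. Harvest time may therefore contribute to these differences, and an effect of infection on the clock that depends on the strain stays open beside it, untested.

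The second pattern is that of the 587 genes called in WT mice at day 12 only 7 were called with the beta-actin 3'/5' ratio as a covariate, the ratio being 1.85 ± 0.10 (SD, n = 3) against 1.41 ± 0.07 (exact permutation p = 0.1, the smallest possible). The same ratio of the control gene Gapdh moved less, 1.11 ± 0.12 (SD) against 0.97 ± 0.09 (SD) in uninfected WT mice, and was not tried as a covariate. The 587 genes kept a median of 0.86 of their change with the covariate (quartiles 0.70 to 1.0) and 0 changed sign. The ratios of the 2 groups do not overlap, so the slope rests on the spread of the ratio within groups (SD 0.03 to 0.20). A slope drawn from so little spread can leave most of a change in place whatever its cause. The kept share therefore cannot decide whether 3' bias of the RNA is the whole cause. Their median absolute change went from 0.60 to 0.54 and their median standard error from 0.149 to 0.199, medians over genes that do not tell which of the 2 ended a given call. Retnla (4.88 ± 0.38 before, 4.34 ± 0.51 after) and Chil3 (2.60 ± 0.27 before, 2.58 ± 0.37 after) stayed called. A contribution of RNA quality to these changes stays open, since the ratio and the group go together, and so does infection itself.

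The third pattern is 27 genes that differed one way by at least 1 between SCID and WT mice in all 6 conditions, 15 of them immunoglobulin genes or in a lymphocyte list. The lack of the lymphocytes' own transcripts as the whole cause is argued against by the 3 of the other 12, Tmem45a, Zfp979 and Plk2, that were higher in all 18 SCID arrays than in any WT array. That is just the number asked for, a threshold set after the values were seen, and Plk2 fell to 0.89 in uninfected mice with probe sets averaged (limma adjusted p = 0.186). The other 9 were lower in SCID mice, of which 3 (Sfi1, Zc3hav1 and Polr3e) were lower in all SCID arrays than in any WT array. A segment of other origin around Prkdc is not the source of these genes within the 200 nearest tested genes, where 0 of the 12 lay (0.15 by chance), but Trbv1, Trav9d-3, Fcrl1 and Ms4a4b among the 12 are lymphocyte genes that test no segment, Tmem45a and Sidt1 lie on that chromosome, and a longer segment stays open. Around the Igh genes 1 of the 12, Serpina1b, was found (0.16 by chance, permutation p = 0.1), too few to decide, so whether such a segment accounts for it cannot be told apart from chance. Other differences between the strains, in genes or in housing, stay open as untested.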

How the results depend on the processing

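The covariate fit, the fit without 2 day 12 arrays and the fit without the 4 muscle arrays were tests chosen only after the result was seen. Of 21 counts of genes, none moved over 1.5-fold with a pseudocount of 4 or 64, no filter, the stricter filter or quantile normalization. The replicate numbers were not taken to pair the mice, since the labels name nothing shared by number. Yet 34 of 36 arrays correlated best with their own number (mean r 0.044 against -0.022 for other numbers), though only 30 of 198 same-number pairs correlated over 0.1. The 3'/5' ratio of the control gene Gapdh was highest in replicate 2 of every group. The arrays thus hold a structure shared by number, of unknown origin, which the main fits leave out. With the replicate block the counts stayed within 1.5-fold (WT day 4, 960; SCID day 12, 22), and of the named calls it ended those of Ighm and Mmp11 in the day 12 response difference. Median centring gave 227 for WT day 8. Median shifts over all genes reached 0.031 with quantile normalization and 0.078 with median centring. Array weights gave 197 for the uninfected strains, 957, 888, 423 and 899 for WT days 2, 3, 8 and 12, 383 and 264 for SCID days 3 and 8. They gave 9, 8, 53 and 39 for the response difference at days 2, 3, 8 and 12, and 193, 61 and 8 for shared genes at days 3, 8 and 12. Only the groups compared gave 778, 200, 211 and 300 for WT days 3, 4, 8 and 12, 31, 336 and 9 for SCID days 2, 4 and 12, and 29 and 26 for the response difference at days 8 and 12. Without a trend SCID days 3, 8 and 12 gave 92, 61 and 8, the response difference at day 8 gave 5, and shared genes at days 3, 8 and 12 gave 57, 11 and 2. Averaged probe sets gave 4 for SCID day 12, 3 and 7 for the response difference at days 2 and 8, and 1 shared gene at day 12. The beta-actin covariate gave 292 and 7 for WT days 2 and 12, 10 for SCID day 12, 7 for the response difference and 0 shared genes at day 12. Without the 2 day 12 arrays SCID day 12 gave 9 and shared genes 3. Without the 4 muscle arrays, which leaves 1 WT day 4 array, WT day 4 gave 161, SCID day 12 gave 10, the response difference at day 4 gave 12, and shared genes at days 4 and 12 gave 61 and 3. Camera called 189 of 496 list tests, 15 with an estimated correlation, and fry 73 (91 for change in either direction). Without each array in turn, counts ranged from 52 to 97 for the uninfected strains, 164 to 583, 172 to 248, 311 to 843, 51 to 109 and 189 to 675 for WT days 2, 3, 4, 8 and 12. They ranged from 57 to 385, 45 to 139, 319 to 1027, 26 to 68 and 5 to 29 for SCID mice, 4 to 8, 4 to 6, 3 to 21, 5 to 9 and 10 to 51 for the response difference, and 35 to 185, 33 to 90, 174 to 391, 7 to 18 and 1 to 6 for shared genes. The cause of these changes was not tested. Medians of the club cell and endothelium lists at WT day 8 reversed with quantile normalization, both to -0.027. Of 473 values of named genes, none reversed, where a change of sign counted only if the main or the alternative fit called the gene. Changes of sign among values called in neither fit were not counted.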

Other observations

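The hypotheses weighed above are not repeated here, and no further test was run; the liver genes named here were chosen only after the result was seen. Some lists passed camera with few members called. Unfolded protein response genes rose in 3 and fell in 1 of 14 cases in WT mice at day 12 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00278, adjusted p = 0.35 with an estimated correlation). The chaperone gene Hspa5 rose by 0.61 ± 0.15, a call lost without 5 of the 6 arrays, with probe sets averaged and with the beta-actin covariate. NK and cytotoxic genes gave 1 fall of 15 in SCID mice at day 2 (6 adjusted over the list alone, camera adjusted p = 0.000482, adjusted p = 0.24 with an estimated correlation). The interferon gamma and Th1 list had no member called in the uninfected strains (1 higher adjusted over the list alone, camera adjusted p = 0.000229 toward SCID mice, adjusted p = 0.355 with an estimated correlation). The interleukin gene Il18 rose by 0.79 ± 0.13 in WT and 0.69 ± 0.13 in SCID mice at day 4. No immediate early gene was called in WT mice at day 2 (camera adjusted p = 0.00265 upward, adjusted p = 0.282 with an estimated correlation). At day 12 the endothelium list had 1 of 14 genes lower in WT mice (2 adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.433 with an estimated correlation). The erythroid list (4 genes) had none called in SCID mice at day 12 (camera adjusted p = 0.0295 upward, adjusted p = 0.143 with an estimated correlation).

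Transcripts of neighbouring tissues differed between single arrays. Heart muscle genes gave 1 fall of 10 in WT mice at day 2 (2 adjusted over the list alone, camera adjusted p = 0.000532, adjusted p = 0.397 with an estimated correlation). The atrial peptide gene Nppa stood at 18692 in WT uninfected replicate 1 against 313 and 1063 in replicates 2 and 3. The same array held Alb at 3885, against 162.8 and 142.9. SCID day 4 replicate 2 held Alb at 14122, Ttr at 6480, Apoa1 at 2977 and the fat cell gene Adipoq at 4106, and Serpina1b at 3737, where the other SCID arrays gave at most 17.7. The adipose list (5 genes) had no member called in WT mice at day 8 (camera adjusted p = 0.0224 upward, adjusted p = 0.552 with an estimated correlation). Of the 10 skeletal muscle genes none was called in SCID mice at day 4 (camera adjusted p = 0.0122 upward, adjusted p = 0.618 with an estimated correlation) or day 8 (camera adjusted p = 0.0148 upward, adjusted p = 0.628 with an estimated correlation).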
